A study of Mus musculus with 2 samples.

How the data were processed

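Single-nucleus RNA profiles of the anterior hypothalamus, including the preoptic area, were taken from male mice of 2 ages. Per the labels, each of the 2 libraries pooled tissue of 5 mice, aged 22 months in one and 3 months in the other. Per the labels' protocols, tissue was homogenised, nuclei were spun through an iodixanol gradient, myelin was removed with magnetic beads, and DAPI-stained nuclei were sorted before loading on a 10x Genomics droplet chip with an aim of 10000 nuclei per sample. Sequencing was done on an Illumina instrument, per the labels' protocols. The strain and the order in which the libraries were made are not given in the sources used here.

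The authors deposited, for each library, an unfiltered matrix of counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalisation. The matrix was written by Cell Ranger 4, per the file headers, and Cell Ranger is also named, per the submitters' processing notes. The genome build, the annotation, the treatment of intronic reads and the use of strand in counting are not given in the sources used here. The feature list holds 32289 features, of which 32285 carry Ensembl identifiers. The other 4 are named for Cre and tdTomato and held 0 UMIs in both libraries. The matrices list 1967507 barcodes for the aged and 1984763 for the young library, with 79107368 and 87520038 UMIs. Gene lengths and gene order were taken by Ensembl identifier from the GENCODE M21 mouse annotation, which gave a length for 32158 features (99.6%). These lengths and this order rest on the gene coordinates of that annotation. Whether the counting used the same annotation is not given in the sources used here.

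All further steps were computed from these counts. Barcodes were called as nuclei in 2 stages. Barcodes above a limit set an order of magnitude below the 99th percentile of the 10000 highest totals were taken first, at 2288 UMIs in the aged and 2328 in the young library. Barcodes below that limit with 500 or more UMIs were taken if a multinomial Monte Carlo test of 10000 draws rejected the profile of barcodes with 100 or fewer UMIs at a Benjamini-Hochberg rate of 0.001. This gave 8185 aged and 10344 young barcodes, of which 1688 and 2243 came from the test. Removal of barcodes with under 500 genes took 39 aged and 30 young barcodes, and removal of those with over 5% mitochondrial UMIs took 44 and 66. The doublet caller Scrublet, as implemented in scanpy and run per library with an expected rate that scaled with the number of nuclei, marked 427 aged (5.27%) and 516 young (5.04%) barcodes, which were left out. This left 7675 aged and 9732 young nuclei, against the aim of 10000 per sample.

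Both libraries were clustered together after scaling to 10000 UMIs and log transformation, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 1. Clusters were named from marker lists chosen before the data were examined, with at least 3 detected markers, and 1 cluster of 23 aged and 51 young nuclei stayed unnamed. That cluster was led by Oxt and Avp, and neuron markers scored highest in it. It stayed unnamed because its median of 1110 UMIs was low and no neuron marker was among its 10 leading genes. Its nuclei are therefore left out of all values for neurons. Names are rebuilt here, since no deposited annotation was used, and each stands for nuclei that resemble that type. No cluster had more markers of another class than of its own among its 10 leading genes. Sox6 and Tcf7l2, listed as precursor lineage markers, led some neuronal clusters by fold against all nuclei. Neurons were clustered again alone by the same method into 25 sub-clusters of 20 or more nuclei in each library and 1 with fewer aged nuclei.

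UMIs were summed per library and class and expressed as CPM, that is, scaled to a common class total. Folds are ratios of CPM with the exact conditional binomial 95% interval, CPM intervals are exact Poisson, and shares carry exact Clopper-Pearson intervals. Intervals of differences between shares were computed with Newcombe's score method. Log2 ratios were taken after adding 5 CPM to both libraries, which pulls genes of low level toward 0. With 1 library per age there is no replicate, no test was made between the ages, and every interval covers counting error only. Age, the pool of mice and the library cannot be told apart.

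Gene lists (29), cell type markers (20 lists), the thresholds above and the rule for named genes were fixed before the data were examined. The rule took genes with 50 or more UMIs in a class, seen in 10 or more nuclei of the library where they were higher and at a level there no lower than in barcodes of 100 or fewer UMIs, and ranked them by the interval bound nearest to a ratio of 1. It named the 10 leading genes in each direction in neurons and the 5 leading genes in each direction in the other main classes and in Avp-high neurons. Gene models with provisional names, mitochondrial genes and haemoglobin genes were skipped. From each list described, the 4 members with the most UMIs or the largest log2 ratio could also be named. Members that ran against the rest of their list, and genes marked as such, were chosen after their values were seen. For each list, members with 20 or more UMIs in a class entered a median log2 ratio, whose percentile was found among 10000 random lists of equal size matched on mean CPM. One of the listed symbols, Clec7a, was not among the features and was not used.

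Thinning compared genes per nucleus at 1000 UMIs. A neuron was called Avp-high if its Avp UMIs exceeded the 1e-06 upper Poisson tail of a droplet of equal UMIs that held only the RNA of barcodes with 100 or fewer UMIs. Oxt-high neurons were called alike. Droplets with 150 to 450 UMIs, taken as droplets without nuclei, were examined after the data were seen, because their RNA profile differed from that of the emptiest barcodes (Pearson r of log2 CPM 0.883 in the aged and 0.769 in the young library, across genes, which are not independent replicates). Alternatives covered the nucleus call, doublets, the mitochondrial limit, the clustering, both ways to subtract free RNA, trimmed mean scaling, the weight of nuclei, neuron sub-cluster composition, the added CPM, the minimum of UMIs, the thinning depth and the Avp limit. The fraction of free RNA for the planned subtraction was the median ratio of other classes' markers to their level in barcodes of 100 or fewer UMIs. Markers of classes that share genes with the class in question were left out of it, a choice made after the data were seen. That fraction was 11.0% in aged and 8.19% in young neurons, while the RNA of an average droplet without a nucleus made up 3.61% and 2.73% of neuron UMIs.

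The interval and percentile steps were checked on simulated Poisson counts drawn from the class means and library sizes. Such counts follow the model of the intervals and hold no variation between nuclei, mice or libraries. The shares below therefore show that the steps work as built and give no error rate for these data. In neurons (17966 genes), 99% of genes simulated 2-fold higher and 98% of those simulated 2-fold lower had intervals that excluded a ratio of 1, as did 4.72% of unchanged genes. In microglia (6790 genes) these shares were 90%, 93% and 4.28%. Of 200 random lists of 15 genes in neurons, 2% fell below percentile 2.5 and 1.5% above 97.5, and in microglia 1.5% and 2%. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9. Trimmed mean of M-values (TMM) factors came from edgeR 4.0.16. They moved log2 ratios by -0.11 in oligodendrocytes and by less in the other classes (-0.01 in neurons, -0.03 in precursors, -0.05 in microglia and -0.05 in astrocytes), and the median of all measured genes in oligodendrocytes was 0.09.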

Results

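Nuclei of the anterior hypothalamus were profiled from a pool of 5 aged male mice (22 months) and a pool of 5 young male mice (3 months), to ask how the cell types of this region, and its vasopressin neurons in particular, differ with age. There was 1 library per age and hence no replicate, so each comparison below describes these 2 libraries, and the 95% intervals given with folds, levels and shares cover counting error only. After filtering, 7675 aged and 9732 young nuclei were compared. Depth was somewhat higher in the aged library in neurons (median 8323 aged and 7810 young UMIs per nucleus), oligodendrocytes (2022 and 1923), microglia (2130 and 1801.5), astrocytes (3417 and 2869) and oligodendrocyte precursors (4291 and 3910). With every nucleus thinned to 1000 UMIs, the median number of genes was 727 aged and 725 young in neurons, 695 and 664 in oligodendrocytes, 789 and 770 in microglia, 691.5 and 673.5 in astrocytes and 721 and 713 in precursors. Thinning left out 9 aged and 3 young neurons, 27 and 39 oligodendrocytes, 4 and 14 microglia, and 1 astrocyte of each library. Without thinning the medians were 3547 and 3393 genes in neurons and 1454 and 1248 in microglia.

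Astrocyte nuclei made up a smaller share of the aged library and oligodendrocyte nuclei a larger one. Astrocytes, the glia that clear transmitter and potassium, were 153 of 7675 aged nuclei (1.99%, 1.69 to 2.33) and 387 of 9732 young nuclei (3.98%, 3.6 to 4.38), a difference of -1.98 percentage points (-2.48 to -1.48). Oligodendrocytes, the myelin-forming glia, were 24.6% (23.7 to 25.6) of aged and 21.0% (20.2 to 21.8) of young nuclei, 3.62 points apart (2.36 to 4.88). Fibroblasts were 17 aged nuclei (0.221%) against 96 young (0.986%), 4.45-fold fewer as a share, and a fibroblast cluster led by Bnc2 held 32 nuclei, all from the young library. For neurons (64.3% and 65.1%), microglia (5.33% and 4.85%) and oligodendrocyte precursors (2.38% and 2.62%) the interval of the difference included 0. Under a looser and a stricter call of nuclei the neuron difference was -3.58 and -3.36 points and that of oligodendrocytes 1.41 and 5.31. Under the stricter call that of microglia was 1.24. Precursors formed a single cluster at Leiden resolution 1. At resolution 2, a cluster with markers of committed precursors, cells that are becoming oligodendrocytes, held 2 of 183 aged nuclei of the precursor class (1.09%, 0.133 to 3.89). It held 22 of 255 young nuclei (8.63%, 5.49 to 12.8), a difference of -7.53 points (-11.7 to -3.53). With each library clustered alone, 0 aged and 22 young nuclei were named as committed precursors. Mural cells (27 and 40 nuclei), endothelial cells (24 and 24) and border macrophages (15 and 24) were too few for comparison of their genes. Whether the dissection, the bead removal of myelin, the density gradient or the DAPI sort differed between the libraries in their effect on these shares was not tested. The fibroblast difference shrank to -0.134 points when at most 1% mitochondrial UMIs were allowed.

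**Figure D1:**
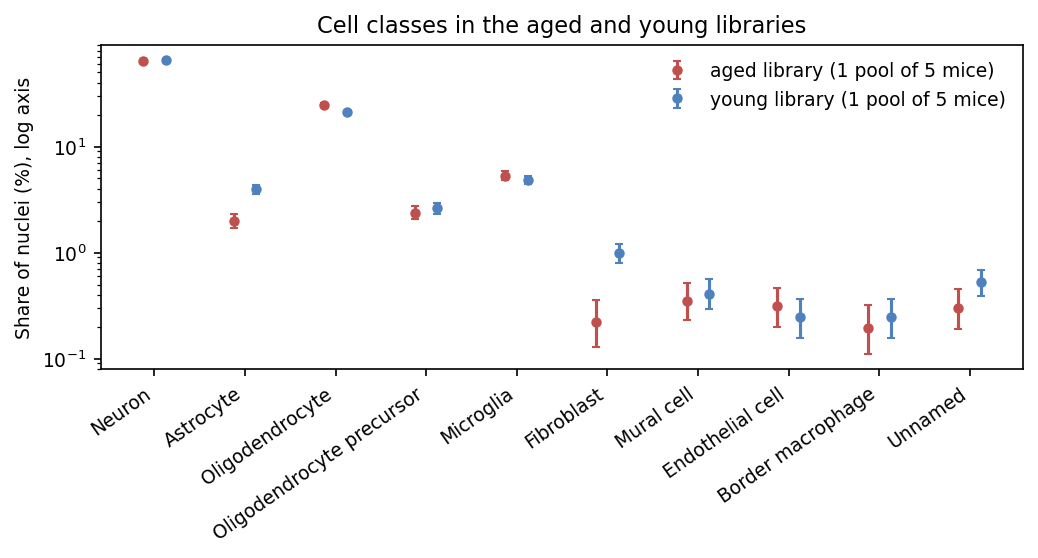
Share of nuclei per cell class (percent, log axis) in the aged and the young library, 1 pool of 5 mice each, with exact Clopper-Pearson 95% intervals that cover counting error only. Astrocytes stood at 1.99% aged and 3.98% young, oligodendrocytes at 24.6% and 21.0%.

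Neurons were mostly inhibitory: 85.9% of aged and 84.3% of young neurons lay in 20 GABAergic sub-clusters, 13.5% and 14.9% in 5 glutamatergic ones, and 0.628% and 0.789% in a mixed sub-cluster led by Slc5a7 and Chat, genes of acetylcholine neurons. A sub-cluster with Tac1 and the dopamine receptor gene Drd1 among its leading genes held 529 aged and 595 young nuclei, and one led by Penk, Drd2 and Adora2a held 472 and 579. One with the dopamine receptor gene Drd3 among its leading genes held 268 and 369. Whether these sub-clusters lie inside the hypothalamus was not tested, so shares and levels of all neurons describe the dissected tissue as a whole. The sub-cluster led by Avp, Oxt, Trh and Sim1 held 221 aged and 285 young nuclei (4.48% and 4.50% of neurons), and the suprachiasmatic-like one, with Rorb, Vip and Avp, held 76 and 103. A glutamatergic sub-cluster led by Pdzrn3, Zeb2 and Slc17a7 held 1 aged and 71 young nuclei, and with 1 library per age such a group can belong to the library and not be a type.

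Avp (ENSMUSG00000037727), which encodes the antidiuretic hormone vasopressin, was at a higher level in aged neurons, while the share of neurons with Avp above background was not distinguishable. Neurons held 6195 Avp UMIs in the aged library (136 CPM, 132 to 139) and 4364 in the young (78.9 CPM, 76.5 to 81.2), a 1.72-fold difference (1.66 to 1.79). Avp-high neurons were 22 of 4933 aged neurons (0.446%, 0.280 to 0.674) and 42 of 6337 young neurons (0.663%, 0.478 to 0.895), and the difference of -0.217 points (-0.494 to 0.0691) included 0. They are a range of values and not a cell type, and 7 aged and 15 young neurons lay within 1.5 times of the limit. The limit itself differed, with a median of 23 Avp UMIs over aged and 16 over young neurons. Of the Avp-high neurons, 13 aged and 25 young lay in the suprachiasmatic-like sub-cluster and 9 and 13 in the sub-cluster led by Avp, Oxt and Sim1, while the remaining 4 young ones lay in other sub-clusters. They held 72.3% of aged and 69.1% of young neuronal Avp UMIs, and 1 aged nucleus alone held 1006 UMIs (16.2%), against 337 (7.72%) for the highest young nucleus. Without that nucleus in each library the log2 ratio was 0.61 in place of 0.75. The unnamed cluster led by Oxt and Avp, of 23 aged and 51 young nuclei, was not counted among neurons in any of these values.

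Avp UMIs were also found in cells that should lack the gene. An Avp UMI was present in 25.5% of aged and 17.2% of young neurons, at median depths of 8323 and 7810 UMIs, in 21.0% and 13.6% of microglia at 2130 and 1801.5 UMIs, and in 22.1% and 13.4% of oligodendrocytes at 2022 and 1923 UMIs. The Avp level in microglia was 114 CPM aged and 80.2 CPM young. In barcodes with 100 or fewer UMIs it was 885 and 461 CPM, and in droplets without nuclei 738 and 638 CPM. Neurons other than the Avp-high ones were at 37.7 CPM aged and 24.5 CPM young, below microglia. Subtraction of the free RNA estimated from other classes' markers turned the neuronal Avp log2 ratio from 0.75 to -0.05, while subtraction of the RNA of droplets without nuclei left it at 0.79. Oxt, which encodes the sister hormone oxytocin, stood the other way in neurons, at 2090 aged UMIs (45.8 CPM) and 4532 young UMIs (81.9 CPM). Oxt-high neurons were 4 aged and 7 young, and 1 young nucleus held 1166 Oxt UMIs (25.7%). Oxt in droplets without nuclei was at 584 CPM aged and 1000.1 CPM young, the same direction as in neurons.

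Beside Avp itself, whose level in Avp-high neurons (21976 CPM aged and 8862 CPM young) is not independent of their selection, Dcc, a netrin receptor, was 2.03-fold higher in the aged Avp-high neurons (1.70 to 2.43; 280 and 230 UMIs), with 104 of the aged UMIs in 1 nucleus. The cell adhesion genes Pcdh7 (2.23-fold, with 41 of the 119 aged UMIs in 1 nucleus) and Plxdc2 (2.47-fold) and the calcium-binding Necab1 (2.25-fold) were also higher. Lower in them were the cation channel Trpm3, 6 and 161 UMIs or 16.1-fold (7.23 to 44.5), the neurexin ligand Nxph1, 10.4-fold (4.62 to 29.0), Clstn2, 5.19-fold, the transcription factor Sox5, 3.93-fold, and galanin (Gal), a peptide made by magnocellular neurons, 25 and 231 UMIs or 5.54-fold (3.66 to 8.74). The nucleus with most UMIs of each gene, counted gene by gene, held 57 of the young Trpm3 UMIs, 29 of the 104 young Nxph1 UMIs and 78 of the young Gal UMIs. Each of these values rests on 22 aged and 42 young nuclei from several sub-clusters. The osmotic and vasopressin list had 11 of 18 members higher in Avp-high neurons (median 0.06, percentile 67.8), with Caprin2, an RNA-binding protein that acts on Avp transcripts and was chosen after its values were seen, 2.06-fold higher (1.38 to 3.09). Myelin genes, which neurons lack, were also higher in aged Avp-high neurons (median 1.70 over 3 members, percentile 99.9). The planned estimate of the free RNA fraction was 24.4% in aged and 7.64% in young Avp-high neurons. RNA of an average droplet without a nucleus made up 3.61% and 2.95% of their UMIs.

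In neurons as a whole, Ide (ENSMUSG00000056999), the insulin-degrading enzyme, was 2.17-fold higher in the aged library (2.06 to 2.29; 3863 and 2161 UMIs in 2425 and 1711 nuclei). Genes of the clustered protocadherin beta family, cell-surface adhesion proteins, were higher, with Pcdhb14 at 2.12-fold (1.90 to 2.38), Pcdhb6 at 3.30-fold (2.49 to 4.42) and Pcdhb2 at 2.64-fold (1.91 to 3.69). Lef1, a transcription factor of the Wnt pathway, was 2.76-fold higher (2.32 to 3.31) on 417 and 183 UMIs, and the magnesium channel Trpm6 was 2.76-fold higher (2.03 to 3.8). The uncharacterised gene model AC149090.1 was 1.79-fold higher (1.77 to 1.82) at 921 and 514 CPM. Tmem40 (4.59-fold), Snx31 (4.35-fold) and Abhd12b (3.33-fold) were higher at under 2 CPM, and 30 of the 72 aged Tmem40 UMIs came from 1 nucleus. Pcdhb genes are close copies of one another, between which the authors' counting could split reads.

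Lower in aged neurons was Lrtm1 (ENSMUSG00000045776), which encodes a leucine-rich repeat membrane protein, by 2.36-fold (2.25 to 2.48; 2067 and 5917 UMIs). Lrtm1 lies within Cacna2d3, so reads of the overlap are uncertain. The Y-linked gene Usp9y was 7.52-fold lower (3.77 to 17.0) on 9 and 82 UMIs, while Kdm5d, Uty, Eif2s3y and Ddx3y, Y-linked genes chosen after their values were seen, stood at folds of 1.03, 1.10, 1.17 and 1.28. Pdzrn3, a ubiquitin ligase, was 2.47-fold lower (2.17 to 2.83), and its log2 ratio of -0.88 became -0.22 with neuron sub-clusters weighted alike in both libraries, while that of Lef1 went from 0.77 to 0.46. The transcripts Grip1os2 (2.33-fold), Usp46os1 (2.31-fold) and Pip5k1bos (2.96-fold), antisense to other genes, were lower, and whether their reads were told apart from those of the partner genes by strand is not given in the sources used here. Il17rb, a cytokine receptor (2.73-fold), Cav1, a caveolae protein (5.03-fold), Taf7l2 (3.78-fold) and Tex21 (4.52-fold) were lower at under 4 CPM, and 98 of the 137 young Tex21 UMIs came from 1 nucleus. The log2 ratio of Cav1 went from -0.23 to -0.09 with neuron sub-clusters weighted alike. Cav1 stood at 0.22 CPM aged and 1.10 CPM young in neurons, below its 2.82 and 4.08 CPM in droplets without nuclei.

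Immediate early genes, which neurons transcribe within minutes of activity, were lower in aged neurons in 19 of 20 cases (median log2 ratio -0.20, percentile 0 of random lists). Nr4a3 was 1.76-fold lower (1.47 to 2.12; 180 and 385 UMIs), Btg2 1.54-fold (1.35 to 1.75), Junb 1.39-fold (1.27 to 1.53) and Nr4a1 1.41-fold (1.27 to 1.56), whereas Jund was 1.23-fold higher (1.16 to 1.31). The median was -0.35 with 1 CPM added in place of 5 and -0.09 with 20. Among 28 hypothalamic neuropeptides 16 were higher and 12 lower (median 0.08, percentile 98.5), and the median was -0.0589 after the planned subtraction of free RNA. Gnrh1, the gonadotropin-releasing hormone, was 3.79-fold lower (3.03 to 4.79; 94 and 432 UMIs), and in droplets without nuclei it stood at 26.3 CPM aged and 71.3 CPM young. Npy was 1.53-fold higher (1.44 to 1.63), Tac1 1.41-fold (1.38 to 1.45), Penk 1.33-fold (1.29 to 1.36) and Sst 1.28-fold (1.23 to 1.32). Tac1 and Penk were among the leading genes of the sub-clusters with Drd1 and Drd2, whose place inside the hypothalamus was not tested.

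The osmotic and vasopressin list, fixed for the hormone named in the study's title, showed no shift as a whole in neurons: 16 members were higher and 14 lower (median 0.01, percentile 62.2). Besides Avp, its largest log2 ratios were those of Nos1, the neuronal nitric oxide synthase, 1.45-fold lower (1.33 to 1.57; 957 and 1677 UMIs), Pdyn, the dynorphin precursor, 1.38-fold higher (1.27 to 1.49), and Caprin2, 1.22-fold higher (1.12 to 1.32). Preoptic thermoregulation genes were likewise split, 6 higher and 8 lower (median -0.01, percentile 33.3), with the leptin receptor Lepr 1.67-fold higher (1.33 to 2.10; 183 and 133 UMIs), the vesicular glutamate transporter Slc17a6 1.16-fold higher (1.10 to 1.23) and neurotensin (Nts) 1.28-fold lower (1.23 to 1.34). Synaptic vesicle genes gave 11 higher and 8 lower (median 0.02, percentile 48.9), with Unc13a, a vesicle priming factor, 1.37-fold lower (1.32 to 1.43) and Rab3a 1.30-fold higher (1.24 to 1.36). Heat shock chaperones were lower in 16 of 20 cases (median -0.04, percentile 6.65). Their median was -0.12 (percentile 0.02) after subtraction of droplet RNA and -0.15 after the planned subtraction of free RNA. Of 24 genes of secretory folding 13 were lower (median -0.03, percentile 11.8). Lysosome and autophagy genes were higher in 17 of 22 cases (median 0.16, percentile 99.96), among them the cathepsin Ctsb at 1.24-fold (1.19 to 1.29) and Lamp1 at 1.22-fold (1.17 to 1.28), and their median was -0.0106 after the planned subtraction of free RNA. All 12 members of MHC class I presentation, which displays peptides to T cells, were higher (median 0.09, percentile 99.9), with H2-K1 at 2.15-fold (1.62 to 2.87; 142 and 80 UMIs) and B2m at 1.49-fold (1.27 to 1.75). Lists named for other cell types were also higher in aged neurons, with 19 of 22 disease-associated microglial genes (median 0.12, percentile 100) and 13 of 15 myelin genes (median 0.11, percentile 98.3). After subtraction of droplet RNA 11 of the 15 myelin genes were higher (median 0.07, percentile 92.9), while the disease-associated median was 0.13 (percentile 100). The disease-associated list shares Ctsb, Ctsd, Ctsl and Cd63 with the lysosome list, so their medians are not independent.

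Microglia, the resident immune cells of the brain, showed higher levels of genes linked to their disease-associated state and lower levels of homeostatic genes in the aged library. Apoe (ENSMUSG00000002985), a lipid carrier, was 8.29-fold higher (7.50 to 9.17; 3610 and 435 UMIs in 264 and 202 nuclei), while in droplets without nuclei it stood at 1405 CPM aged and 1827 CPM young. Of 22 disease-associated genes 20 were higher (median 0.68, percentile 100), including the integrin Itgax at 30 and 1 UMIs (30-fold, 4.98 to 1222), the receptor kinase Axl at 34 and 3 UMIs (11.3-fold, 3.56 to 57.6) and the tetraspanin Cd9 at 1.71-fold (1.55 to 1.90), whereas Tyrobp was 1.25-fold lower (1.08 to 1.45) and Trem2 stood at 897 and 894 UMIs. Of 15 homeostatic genes 14 were lower (median -0.41, percentile 0.02), with Fcrls 1.77-fold (1.56 to 2.02), Olfml3 1.65-fold (1.37 to 1.99), the ligand Selplg 1.41-fold (1.29 to 1.53) and the fractalkine receptor Cx3cr1 1.31-fold lower (1.22 to 1.40). Tgfbr1 ran against them at 1.05-fold higher (0.987 to 1.11).

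Interferon response genes were higher in 18 of 20 cases in microglia (median 0.79, percentile 100), with Sp100 at 3.52-fold (2.14 to 6.02; 74 and 21 UMIs), Samd9l at 6.24-fold (2.15 to 24.7; 25 and 4 UMIs) and Trim30a at 1.76-fold (1.38 to 2.26). All 11 members of MHC class I presentation were higher (median 0.63, percentile 100), led by H2-D1 at 3.00-fold (2.45 to 3.68; 390 and 130 UMIs) and H2-K1 at 2.26-fold (1.82 to 2.82). The secretory folding genes went the other way, 16 of 22 lower (median -0.23, percentile 0.05), with the chaperone Hspa5 1.44-fold (1.19 to 1.75) and Manf 1.55-fold lower (1.19 to 2.03). All 4 complement members measured were lower (median -0.13, percentile 35.6), such as C1qa at 1.16-fold (1.09 to 1.23). By the fixed rule, Rai14 (20.3-fold, 6.63 to 101; 61 and 3 UMIs), the transcriptional repressor Trps1 (7.51-fold, 4.75 to 12.5), the inhibitory receptor Lilrb4a (8.99-fold, 4.32 to 21.6) and the chemokine Ccl4 (19.6-fold, 6.40 to 97.9, with 28 of 59 aged UMIs in 1 nucleus) were higher. Tmigd3 (3.57-fold, 2.23 to 5.94), the cytokine receptor Il7r (2.75-fold, 1.86 to 4.15), Lysmd4 (1.83-fold, 1.63 to 2.06), Myo18b (2.88-fold) and Vxn (2.78-fold) were lower. RNA of an average droplet without a nucleus made up 15% of aged and 12.4% of young microglial UMIs.

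Several genes were more than 5-fold higher in aged oligodendrocytes, among them the complement gene C4b. C4b (ENSMUSG00000073418) was 34.4-fold higher in the aged library (24.1 to 50.9), on 1022 UMIs in 519 of 1891 nuclei against 31 UMIs in 31 of 2046. Fam155a (ENSMUSG00000079157), a subunit of the sodium leak channel complex, was 23.8-fold higher (20.1 to 28.2; 3324 and 146 UMIs), with a log2 ratio of 4.38 that became 2.23 with doublets kept and 7.40 with free RNA subtracted, the cadherin Cdh8 5.37-fold (4.61 to 6.28; 1029 and 200 UMIs), the transcriptional coactivator Eya4 7.23-fold (5.45 to 9.75) and the protease inhibitor Serpina3n 10.0-fold (4.85 to 24.1; 77 and 8 UMIs). Lower were the stress-inducible chaperone Hspa1a, 11-fold (4.02 to 42.1; 4 and 46 UMIs), the guidance cue Sema3d, 6.15-fold (3.33 to 12.4), the mannosidase Man1a, 2.89-fold (2.40 to 3.49), the peptide transporter Slc15a2, 3.39-fold (2.14 to 5.58), and Nckap5, 2.55-fold (2.08 to 3.15). C4b has a near-identical copy in C4a and Hspa1a in Hspa1b, and reads could be split between the copies in counting.

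Heat shock chaperones were lower in 15 of 19 cases in oligodendrocytes (median -0.31, percentile 0). Beside Hspa1a, Hspa1b was at 1 and 33 UMIs (31.6-fold lower, 5.29 to 1286), Hspa4l 2.14-fold (1.79 to 2.57), Hsp90ab1 1.36-fold (1.29 to 1.44) and Cryab 1.37-fold lower (1.27 to 1.47). Secretory folding genes were lower in 17 of 22 cases (median -0.14, percentile 0), among them Hspa5 (1.39-fold, 1.22 to 1.58) and Calr (1.42-fold, 1.24 to 1.63). Myelin genes moved little: 7 were higher and 8 lower (median -0.08, percentile 6.19), with Mbp 1.17-fold lower (1.14 to 1.20) and Cnp 1.15-fold higher (1.07 to 1.23). Cholesterol synthesis genes were lower in 14 of 24 cases (median -0.05, percentile 0.67), with Cyp51 1.38-fold lower (1.12 to 1.70) and Pmvk 1.63-fold higher (1.22 to 2.20). Under a stricter call of nuclei the cholesterol median was 0.0315. Cdkn1a, a cell cycle inhibitor on the senescence list, was 3.6-fold higher (2.16 to 6.26; 69 and 20 UMIs), while the median of that list was 0.03 (percentile 30.7, 5 members). Neuronal transcripts moved with the aged oligodendrocytes: synaptic vesicle genes were higher in 17 of 19 cases (median 0.35, percentile 100), and this median was 0.11 (percentile 83.0) after subtraction of the RNA of droplets without nuclei, which made up 15.4% of aged and 11.4% of young oligodendrocyte UMIs. Oligodendrocytes came from 2 clusters with 1482 and 409 aged and 1448 and 598 young nuclei.

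Oligodendrocyte precursors, the dividing cells that give rise to oligodendrocytes, had fewer transcripts of differentiating cells in the aged library. Of 12 differentiation genes 11 were lower (median -0.86, percentile 0), with Enpp6 12-fold (6.34 to 25.5; 10 and 156 UMIs), Bmp4 6.40-fold (2.74 to 18.3; 6 and 50 UMIs), Tcf7l2 2.51-fold (2.05 to 3.09) and Bcas1 1.85-fold lower (1.66 to 2.07), while Neu4 was 1.21-fold higher (1.03 to 1.42). Myelin genes were lower in 10 of 12 cases (median -0.59, percentile 0). By the fixed rule the transcription factor St18 was 26.5-fold lower (14.2 to 55.7; 10 and 345 UMIs), Mbp, a major myelin protein, 5.56-fold (4.27 to 7.33), Chn2 4.32-fold (3.05 to 6.28) and Frmd4a 5.09-fold (4.49 to 5.77), with 530 of the 1927 young Frmd4a UMIs in 1 nucleus. These values move with the committed precursors counted above, and all 10 aged Enpp6 UMIs lay in 1 nucleus. Enpp6, Bmp4, Tcf7l2, Bcas1 and Neu4 are also among the markers used to name the committed cluster. The differentiation list is therefore not independent of the share of committed precursors. Without the 2 aged and 22 young committed nuclei, the differentiation median was -0.11, the myelin median 0.18, and the log2 ratios were -1.05 for Enpp6, -0.44 for St18, -0.19 for Chn2, 0.16 for Mbp and 0.24 for Frmd4a.

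Interferon response genes were higher in 8 of 9 cases in the precursors (median 0.90, percentile 100), with Rnf213 at 3.26-fold (1.78 to 6.23), Samd9l at 3.30-fold (1.77 to 6.46), Irf9 at 3.18-fold (1.41 to 7.85) and Ifi27 at 2.06-fold (1.53 to 2.78). The MHC class I gene H2-D1 was 2.23-fold higher (1.52 to 3.29), all 4 members of its list were higher (median 0.63, percentile 99.6), and Pcdhb9 was 2.99-fold higher (1.87 to 4.89). Proliferation genes were too scarce for a statement, with 3 members measured (median 0.55, percentile 95.3) and no interval that excluded a ratio of 1.

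**Figure D2:**
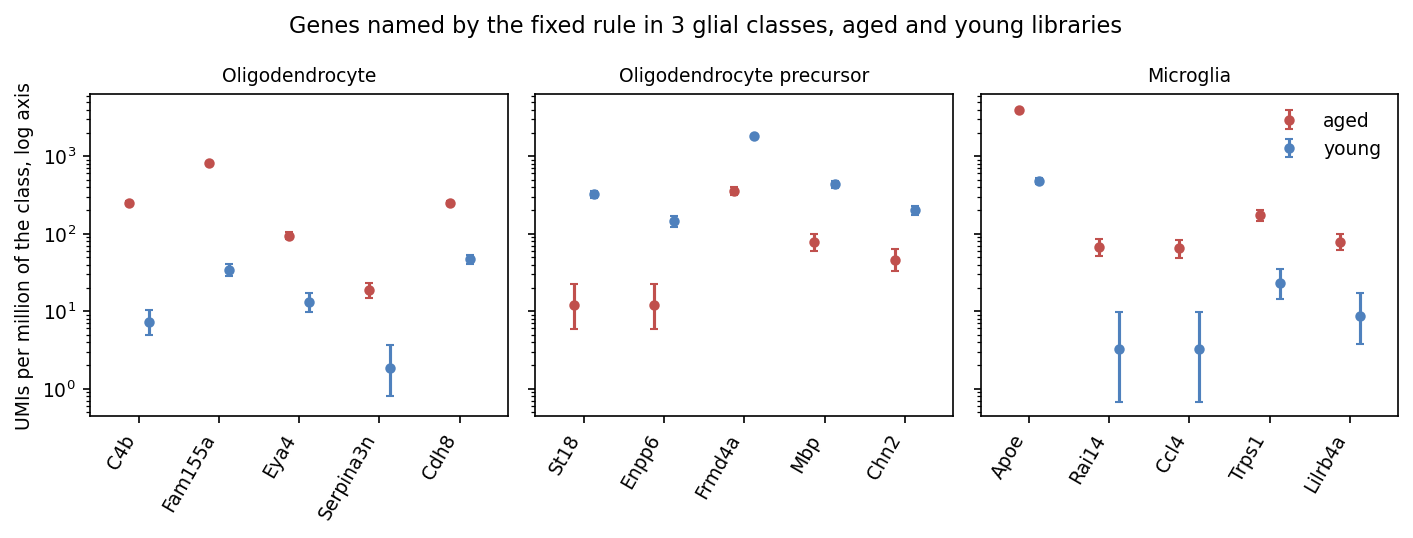
Levels (CPM of the class, log axis) in the aged and the young library of genes named by the fixed rule, those higher in aged oligodendrocytes and microglia and those lower in aged oligodendrocyte precursors, with exact Poisson 95% intervals that cover counting error only. C4b stood at 249 and 7.24 CPM in oligodendrocytes, and St18 was lower in aged precursors on 10 and 345 UMIs.

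Astrocytes, at 153 aged and 387 young nuclei, had higher levels of several reactive genes in the aged library and little difference in transport genes. C4b was 3.14-fold higher (2.23 to 4.45; 84 and 60 UMIs), Ggta1 3.09-fold (1.55 to 6.28) and the filament protein Gfap 2.06-fold (1.35 to 3.14; 46 and 50 UMIs), and the reactive list had a median of 1.05 (percentile 100, 4 of 6 members higher), with S1pr3 3.86-fold lower (1.18 to 19.9; 3 and 26 UMIs). Transport genes were split, 6 higher and 7 lower (median -0.03, percentile 36.0). The potassium channel Kcnj10 was 1.63-fold lower (1.19 to 2.26), the connexin Gjb6 1.53-fold lower (1.22 to 1.94), the glutamate transporter Slc1a2 1.09-fold lower (1.04 to 1.15) and Atp1b2 1.20-fold higher (1.02 to 1.41). The water channel Aqp4, chosen after its values were seen, was at a fold of 1.12 (0.920 to 1.36). Interferon response genes were higher in 9 of 10 cases (median 0.77, percentile 100), with Rtp4 at 3.81-fold (1.65 to 9.32). By the fixed rule the transcription factor Dach1 was 4.95-fold higher (3.15 to 7.97; 64 and 29 UMIs), AC149090.1 2.60-fold, the Tie2 ligand Angpt1 2.17-fold and the sialyltransferase St6galnac5 2.11-fold. Lrrc19 (4.68-fold), Fez2 (4.90-fold), Rgs3, a regulator of G protein signalling (3.06-fold), Pard3bos1, antisense to another gene (2.92-fold), and the histone deacetylase Hdac4 (2.23-fold, 1.69 to 2.98) were lower. Droplet RNA made up 9.65% of aged and 7.77% of young astrocyte UMIs.

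Genes of the cytosolic ribosome were higher in the aged library in all 5 main classes: 38 of 38 in neurons (median 0.26, percentile 100), 38 of 38 in oligodendrocytes (0.42, percentile 100), 36 of 38 in precursors (0.37, percentile 100), 30 of 38 in astrocytes (0.29, percentile 100) and 29 of 38 in microglia (0.18, percentile 99.9). Among lists matched also on gene length, the ribosomal percentiles were 99.94 in neurons, 99.98 in oligodendrocytes, 93.8 in precursors, 93.6 in astrocytes and 82.6 in microglia. In neurons Rpl13 was 1.23-fold higher (1.19 to 1.27). Nuclear genes of oxidative phosphorylation were higher in 44 of 48 cases in neurons (median 0.19, percentile 100), such as Ndufa4 at 1.25-fold (1.21 to 1.29), and in 48 of 48 in oligodendrocytes (median 0.31, percentile 100). Genes of the mitochondrial genome were split in neurons, 9 higher and 4 lower (median 0.20, percentile 99.98), with mt-Nd4l 2.01-fold higher (1.91 to 2.12) and mt-Co3 1.06-fold lower (1.04 to 1.08). Free RNA moved with the ribosomal and oxidative phosphorylation genes: droplets without nuclei held a median of 333 UMIs in the aged library and 234 in the young. Per droplet these were 13.3 and 9.09 ribosomal protein UMIs, and 11.1 and 8.13 of oxidative phosphorylation. The mitochondrial share of the droplets went the other way, at 0.805% aged and 1.39% young. Subtraction of droplet RNA raised the mitochondrial genome median in neurons to 0.27. Subtraction of the droplet RNA brought the ribosomal median to 0.13 in neurons (percentile 99.99), 0.24 in oligodendrocytes (percentile 100) and -0.06 in microglia (percentile 4.3). It was 0.32 in precursors (percentile 100) and 0.18 in astrocytes (percentile 97.7) after that subtraction. Subtraction of the larger planned estimate brought it to -2.35 in neurons and -0.11 in oligodendrocytes, and the oxidative phosphorylation median to -1.54 and -0.17. Over 162 pairs of a list and a class, 44 medians lay above the central 95% of random lists and 11 below it. Chance would give 8.1 in all if genes and pairs were independent. Lists share members, Avp-high neurons are part of the neurons, and the classes share the free RNA of their library. The value of 8.1 is therefore no chance rate for these data.

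**Figure D3:**
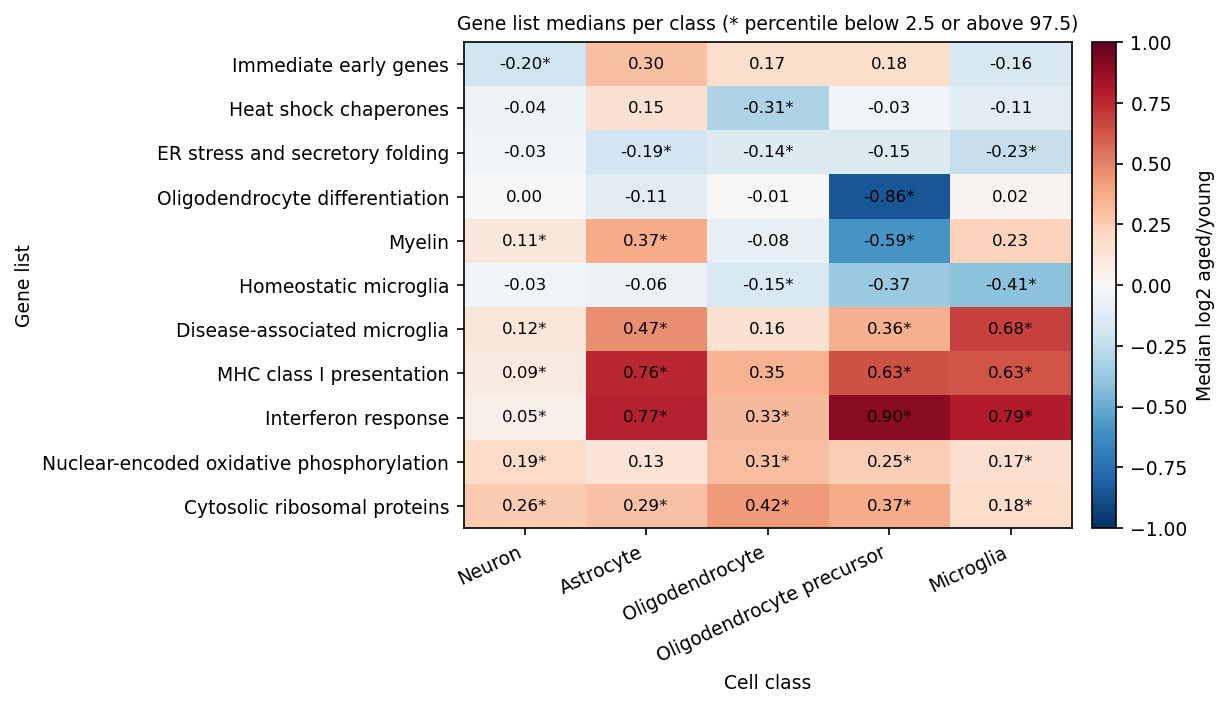
Median log2 ratio (aged over young, 5 CPM added) of 11 of the 29 gene lists in the 5 main classes as colour and number, with an asterisk where its percentile among 10000 random lists lay outside the central 95%. Ribosomal genes had positive medians from 0.18 in microglia to 0.42 in oligodendrocytes.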

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

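The droplets without nuclei and each test below were examined only after the results were seen, except the tests of gene length in neurons and of a gain of the whole Ide region, which were set before. The first values come from droplets without nuclei, which lie outside the counts of nuclei. C4b and Hcrt were picked from the genes of the fixed lists by the lower bound of their aged over young fold in these droplets. Their folds there are therefore not independent of that choice. C4b was at 32.0 CPM in these droplets of the aged library and 5.38 CPM in the young, 5.94-fold higher (4.74 to 7.53). Hcrt, the orexin precursor of lateral hypothalamic neurons, was at 40.7 CPM aged and 2.85 CPM young, 14.3-fold higher (10.6 to 19.7), and in neurons it was 3.43-fold higher (2.54 to 4.70; 167 and 59 UMIs).

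C4b, Fam155a, Eya4, Serpina3n and Cdh8 were higher in aged oligodendrocytes. Droplet RNA accounted for at most 10.3% of the aged oligodendrocyte UMIs of these genes (Serpina3n), and for 1.98% of those of C4b, which argues against free RNA as the source. Neurons, astrocytes or precursors caught with oligodendrocytes would raise all their markers, whose median log2 ratios in oligodendrocytes were 0.33, -0.02 and 0.35, far below those of the 5 genes. A response of oligodendrocytes to age may account for the pattern as a hypothesis, and a difference between the pools of mice or the library batches stays open, since 1 library per age cannot separate them.

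Ribosomal protein genes were higher in the aged library in the 5 main classes, and oxidative phosphorylation genes in most. A bias for short genes is argued against as the whole cause in neurons and oligodendrocytes, where the ribosomal medians of 0.26 and 0.42 lay at percentiles 99.94 and 99.98 of lists matched on expression and gene length, but such lists had medians of 0.16 and 0.29 themselves, so a part by gene length stays open. It also stays open in astrocytes, precursors and microglia, where the ribosomal percentiles were 93.6, 93.8 and 82.6. Those of oxidative phosphorylation were 40.5, 70.3 and 95.8 there, against 99.79 in neurons and 99.17 in oligodendrocytes. More free RNA per droplet also stays open: the excess of ribosomal protein UMIs per aged neuron was 1.23 times the difference between aged and young droplets without nuclei (lower bound 1.19), under the bound of 2 set for it but above the value of 1 that equal free RNA in every droplet would give. In the other main classes this ratio was 1.35 in precursors (lower bound 1.15), 1.01 in oligodendrocytes (lower bound 0.956), 0.83 in astrocytes and 0.61 in microglia. An increase of these transcripts with age was not tested apart from these explanations.

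Ide was higher in the aged library in each of the 5 main classes, from 2.17-fold in neurons to 2.29-fold in microglia. A shift of the whole library is argued against by the UMIs per neuron over all genes, taken before scaling since scaling would hide such a shift, at a log2 ratio of 0.0836 (1.06-fold) beside 2.30-fold for Ide per neuron (2.18 to 2.42), and a gain of the whole stretch from Btaf1 to Ide by a median of 0.0294 over the 4 genes of that stretch other than Ide. Separate gains of Btaf1 and of Ide stay open, since both were higher in every class, with a lowest log2 ratio of 0.63, as a difference in copy number between the mice might give. A gain that carries Ide and Fgfbp3 is known to segregate in C57BL/6J mice, and Fgfbp3 was 2.36-fold higher in neurons (2.12 to 2.63), 2.01-fold in precursors (1.14 to 3.61), 2.5-fold in microglia (1.16 to 5.82) and 1.90-fold in astrocytes (1.11 to 3.25), but at 1.17-fold in oligodendrocytes (0.926 to 1.47). The strain is not given in the sources used here, and a response to age stays open as well.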

How the results depend on the processing

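The call of nuclei against the droplet profile, the Avp limit from that profile, the droplet subtraction and the runs without the committed precursors or without the neuron of each library with most Avp UMIs were chosen after the data were seen. Of the main results under all settings, 315 values stayed within their interval, or for the counts of nuclei within 1.5 times, 22 moved beyond it and 2 reversed. That count leaves out the ribosomal lists, most other pairs of a list and a class, and genes other than Avp. Outside it, 13 list medians reversed with free RNA subtracted by the planned estimate. There 1 list median each reversed with droplet RNA subtracted, with doublets kept and without committed precursors, as did 2 gene levels without committed precursors. Where no construction is named the cause was not tested. With free RNA subtracted by the planned estimate, the Avp log2 ratio went from 0.75 to -0.0496, the neuropeptide median in neurons from 0.08 to -0.0589, the lysosome median in neurons to -0.0106 and the heat shock median in astrocytes to -0.00291. For Avp that estimate exceeded the level in neurons other than the Avp-high ones. The same subtraction took the ribosomal medians to -2.35 in neurons, -2.54 in astrocytes, -0.11 in oligodendrocytes, -0.42 in precursors, -0.997 in microglia and -2.94 in Avp-high neurons, and those of oxidative phosphorylation to -1.54 in neurons, -0.17 in oligodendrocytes, -0.00535 in precursors, -2.21 in microglia and -2.43 in Avp-high neurons, with the mitochondrial genome at -0.65 in Avp-high neurons. With droplet RNA subtracted, the medians were 0.12 for oxidative phosphorylation in neurons, -0.52 for heat shock in oligodendrocytes and -0.0602 for ribosomal genes in microglia. Within their intervals, medians changed sign for preoptic genes in neurons (0.0234 with sub-clusters standardised), synaptic vesicle genes in neurons (-0.0632) and transport genes in astrocytes (0.0239) with free RNA subtracted, and cholesterol synthesis in oligodendrocytes (0.0315 under a stricter call). With doublets kept, the median of glutamate and GABA receptors in oligodendrocytes was -0.022. Avp was at 0.54 with at most 1% mitochondrial UMIs, 0.64 as a mean of per-nucleus proportions, 0.66 with 20 CPM added and 0.61 without the neurons of most Avp UMIs. Immediate early genes in neurons had medians of -0.35 with 1 CPM and -0.0907 with 20 CPM added, and proliferation genes in precursors 0.73 with 1 CPM added, since the added CPM sets the scale of low genes. Without committed precursors, the medians in precursors were 0.18 for myelin and -0.11 for differentiation genes, with Frmd4a at 0.24 and Mbp at 0.16, since those nuclei carry these transcripts. Differences in share were -3.58 points for neurons and 1.41 for oligodendrocytes under a looser call of nuclei, -3.36 for neurons, 5.31 for oligodendrocytes and 1.24 for microglia under a stricter one, and -0.134 for fibroblasts with at most 1% mitochondrial UMIs. Without thinning, aged over young genes per nucleus were 1.05 in neurons, 1.17 in astrocytes, 1.08 in oligodendrocytes, 1.08 in precursors and 1.17 in microglia, as depth was higher in the aged library. The astrocyte share difference ranged from -2.14 to -1.95 points, the Avp-high difference from -0.309 to -0.0317, and the median of disease-associated genes in microglia from 0.39 to 0.80. The C4b log2 ratio in oligodendrocytes ranged from 3.31 to 4.92, that of Fam155a from 2.23 with doublets kept to 7.40 with free RNA subtracted, and that of Apoe in microglia from 2.87 to 3.92. Of 70 gene levels, 34 moved with 20 CPM added, 26 with 1 CPM added, 14 with free RNA subtracted, 13 with per-nucleus proportions and 11 with doublets kept. No paired analysis was possible because the groups share a single replicate number and no test was made. The number of Avp-high neurons, 22 aged and 42 young, limits what can be said of them.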

Other observations

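The gene families, genes and tests in this part were chosen after their values were seen. The clustered protocadherin beta genes, adhesion molecules of which each neuron uses its own subset, summed to 106 CPM in aged and 62.6 CPM in young neurons, 1.69-fold higher (1.61 to 1.76). Of 21 measured members 20 were higher, with Pcdhb3 at 3.96-fold (134 and 41 UMIs), Pcdhb9 at 2.05-fold (333 and 197 UMIs) and Pcdhb19 at 1.92-fold (365 and 231 UMIs), while Pcdhb18 was at 0.963-fold. In oligodendrocytes the family was 2.08-fold higher (1.70 to 2.56; 287 and 144 UMIs). In precursors its sum was 1.58-fold higher (1.25 to 1.99; 167 and 138 UMIs), with Pcdhb9 at 62 and 27 UMIs, while 1 of 3 measured members was higher (median -0.15, percentile 23.5). The alpha and gamma clusters were 1.21-fold (1.12 to 1.31) and 1.20-fold (1.15 to 1.26) higher in neurons. Of the Y-linked genes in neurons, the family as a whole was 1.14-fold higher (1.11 to 1.16) and Usp9y lower.

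Apoe was higher in microglia by far more than in the other main classes, where its folds were 1.22 in neurons (1.17 to 1.28), 1.40 in oligodendrocytes (1.36 to 1.45), 1.42 in precursors (1.35 to 1.5) and 1.18 in astrocytes (1.14 to 1.22). C4b was higher in precursors too, at 20 and 1 UMIs (26.0-fold, 4.17 to 1079). The nuclear long non-coding RNA Neat1 was 1.48-fold higher in oligodendrocytes (1.44 to 1.53; 8469 and 5959 UMIs), 2.27-fold in microglia (1.67 to 3.11), 1.40-fold in astrocytes (1.01 to 1.92) and 1.31-fold in neurons (1.14 to 1.5), and at 0.698-fold in precursors (0.346 to 1.35). Disease-associated microglial genes were also higher outside microglia, in 9 of 11 cases in astrocytes (median 0.47, percentile 100), 11 of 12 in precursors (median 0.36, percentile 99.8), 19 of 22 in neurons (median 0.12, percentile 100) and 6 of 8 in Avp-high neurons (median 0.50, percentile 99.7), and in 15 of 17 in oligodendrocytes (median 0.16, percentile 93.6; 0.23 and percentile 99.45 with droplet RNA subtracted). Of 21 lysosome and autophagy genes 14 were higher in astrocytes (median 0.38, percentile 99.96). The lysosome list shares Ctsb, Ctsd, Ctsl and Cd63 with the disease-associated one. In droplets without nuclei Lyz2, a gene of myeloid cells, was 2.20-fold higher in the aged library (1.92 to 2.52), and Gfap 1.87-fold (1.53 to 2.29).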
